A study of Mus musculus with 6 samples.

How the data were processed

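Gene expression was measured in sciatic nerves of mice aged 1 month, in 3 pools from control littermates (Ctrl) and 3 pools from OGT_SCKO mice, with 1 array per pool. Per the labels, total RNA was labelled chemically with a red dye and each array carries 1 sample. Per the series description the pools are independent. The number of animals in a pool is not given in the sources used here, and p-values measure the spread between pools.

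Per the file headers, the spot intensity values were made with Agilent Feature Extraction 11.5.1.1, which subtracted the background, corrected trends across the array and replaced very low values by a surrogate. The deposited intensity values were not normalised between arrays. Other flags in the same files state whether a spot was well above background, saturated or an outlier. The authors' deposited table of log2 values has the same distribution in each column, so it was treated as quantile normalised from its values. It was used as an alternative, and what else was done to it is not given in the sources used here. Each array held 43020 spots that were not controls, for 39429 probes. Between 59.0% and 65.2% of the probes were well above background on an array and no spot was saturated. The 75th percentile of the processed signal ran from 2749 in Ctrl 2 to 6136 in OGT_SCKO 2. The number of arrays limits the precision.

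The main values were log2 of the processed signal minus the 75th percentile of each array. Control spots and outlier spots were left out, and 40 probes lost at least 1 array in that way. Spots of a probe were averaged. Probes were kept where they were well above background on all arrays of at least 1 group, which left 24268 probes. A gene was represented by the kept probe with the highest mean over all 6 arrays, which gave 19046 genes, 4284 of them with several kept probes. Of 124 genes selected for naming, 23 had several kept probes, and the probes of Fdft1 and Vwf differed in the sign of their change. In Pdzk1ip1, Gstm1 and Tpsb2 the other probe did not pass the test. Probes were named through their accession in a RefSeq gene table of assembly GRCm38.p6, which matched 27649 probes and updated 1710 symbols. The other 11780 probes kept the name in the files. Probe positions are those in the files, on the older build mm9. Exon and UTR annotation of that build was not used here. Among 15294 tested genes with a chromosome in both, the files place the probe of 68 on another chromosome than the gene table does, Gstm1 alone among the genes selected for naming. Of the genes tested, 14315 had a gene symbol and 4731 a clone name or none.

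Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05, and counts at 2-fold or more are given beside that. Errors of fold changes are standard errors of the limma fit unless an SD is named. A probe that was not well above background on any array of a group has only a bound there. For genes with no probe above background there the change is given as at least N-fold, the bright group's mean set against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Genes with a bound under 1 have no fold.

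The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named Ogt, the 12 largest rises and 12 largest falls among changed genes with no overlap between groups and a gene symbol, and up to 4 members per list with the smallest p, plus Jun. Clcf1, Igf2, Mbp, Egr2, S100a8, Ly6g and Col4a1 lie outside the rule and are given from the main fit only. Whether the changes among them hold with slide as a block or the other alternatives is not given. Some genes are not reported here. Of 28 lists, 27 were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists. The pathway lists were O-GlcNAc cycling, myelin structure, myelin regulators, cholesterol, fatty acid synthesis, repair Schwann cell genes, immature Schwann cell genes, AP-1, trophic factors, chemokines, interferon response, cell division, stress response, NRF2, glycolysis and extracellular matrix. The cell type lists were macrophage, T and NK cell, neutrophil and mast cell, fibroblast, perineurial, endothelial, mural, adipocyte, skeletal muscle, neuronal and erythroid markers. The last list, of sex-linked genes, served as a check of the pools. Beside camera's preset, the estimated correlation and fry were run.

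The alternatives were quantile or median scaling, normexp background correction with an offset of 50, no filter on dim probes or a filter on all 6 arrays, the mean of a gene's probes, the deposited log2 values, slide as a fixed or random block, the arrays of slide 1 alone, a block by replicate number, other variance models, a stricter threshold and leaving out each array in turn. Slide 1 held Ctrl 2 and all 3 OGT_SCKO pools and slide 2 held Ctrl 1 and Ctrl 3, so slide and group overlap in part. Within slide 1, and with slide as a fixed block, OGT_SCKO is set against Ctrl 2 alone, so the estimates of the 2 fits are the same by construction. They are not separate support, and Ctrl 2 is assumed to vary like the other pools.

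The gene test was tested on simulated data for OGT_SCKO against Ctrl with 19046 genes, 200 of them changed. It recovered 63.0% of the genes changed by 1 on the log2 scale and 98.0% of those changed by 2. Of its 166 calls 5 were false. In the data 4440 genes were called, and estimated array weights ran from 0.26 (OGT_SCKO 2) to 6.53 (OGT_SCKO 3). The simulation gave a gene the same spread on every array and held no slide effect. These shares thus do not carry over to the real gene test. For the same comparison and 19046 genes, camera called 0 of 26 unshifted simulated lists. The simulated genes varied independently, so this does not test camera on lists whose genes vary together. Among the real lists the estimated correlation reached 0.71, for interferon response genes. The co-variation and matched-list tests of the closing section were tested on 200 simulated sets each. Co-variation passed the 95th percentile in 100.0% of sets with a shared factor and in 7.0% of independent sets. Matched lists lay below the 5th percentile in 100.0% of lists lowered by 0.5 and in 6.0% of unshifted lists. These lists were drawn from all signal levels with no signal trend, and the lowering exceeds the myelin list's median of -0.33. The share found thus does not carry over to the myelin list.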

Results

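Sciatic nerve RNA was profiled in 3 pools of control littermates and 3 pools of OGT_SCKO mice aged 1 month. OGT is the enzyme that attaches O-GlcNAc, a single sugar, to nuclear and cytoplasmic proteins. The series title asks how this modification in Schwann cells, the glia that wrap peripheral axons, bears on the transcription factor JUN. Correlations across genes were 0.979 to 0.995 between pools of a group and 0.949 to 0.976 between groups, with genes not being independent replicates. The first principal component held 68.7% of the variance and separated the groups.

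Ogt itself fell in OGT_SCKO nerves. The signal of its probe on chromosome X at 98879145 to 98879204 (mm9) went from 0.31 ± 0.18 (SD, n = 3) in Ctrl to -0.97 ± 0.070 (SD, n = 3) on the log2 scale relative to the array's 75th percentile. This was 41.3% of the control level, a log2 fold change of -1.28 (SE 0.13, limma adjusted p = 0.00117). A second Ogt probe, at 98874662 to 98877529, stood at 50.5% of control (log2 fold change -0.99, limma adjusted p = 0.0241). The Ctrl values of the first probe were 0.46, 0.35 and 0.11 and the OGT_SCKO values -0.89, -1.01 and -1.01. The exact two-sided permutation test gave p = 0.1 for both probes, the smallest that 3 against 3 pools allow. Which part of Ogt was deleted is not given in the sources used here, and a probe outside that part checks nothing. With slide as a block, which sets OGT_SCKO against Ctrl 2 alone, the log2 fold change was -1.32 (limma adjusted p = 0.0215), and the same contrast within slide 1 had an adjusted p of 0.0535. Oga, which removes O-GlcNAc, fell 2.23-fold (log2 fold change -1.16, SE 0.10, limma adjusted p = 0.000827), and with normexp background correction its call ended (1.54-fold, adjusted p = 0.163). Among 12 measured genes of O-GlcNAc cycling and the hexosamine pathway, Gfpt2 rose 1.56-fold (adjusted p = 0.0727 with slide as a block), Ogt and Oga fell and 9 did not pass the test. Adjusted over the list alone, 2 were higher and 3 lower. The list as a whole was not called (limma camera adjusted p = 0.958), and its median of 0.02 differed in sign from its mean of -0.13 and its test.

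**Figure D1:**
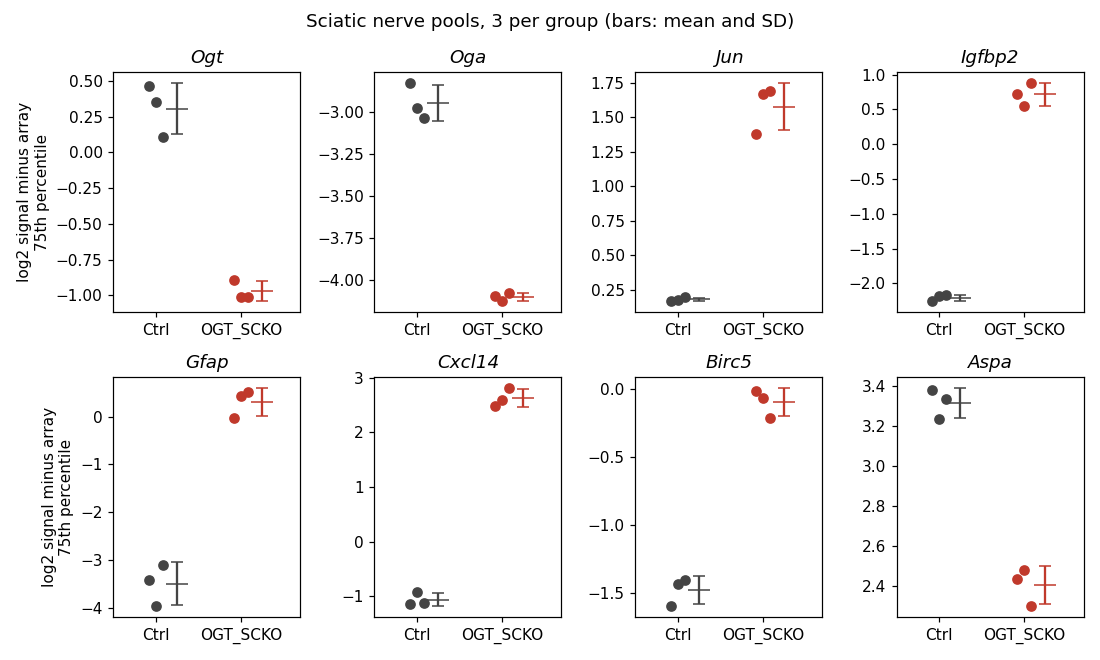
Each panel plots the log2 signal minus the array's 75th percentile for a gene in 3 Ctrl pools (grey) and 3 OGT_SCKO pools (red), with mean and SD as bars; vertical axes differ between panels and do not start at 0. Ogt, Oga and Aspa are lower and Jun, Igfbp2, Gfap, Cxcl14 and Birc5 higher in all 3 OGT_SCKO pools than in any Ctrl pool.

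Across the nerve, 4440 of 19046 genes changed (limma, 23.3%), 2128 higher and 2312 lower in OGT_SCKO. By at least 2-fold, 655 genes rose and 622 fell. Of all calls with quantile normalisation 2572 were higher and 2344 lower, so the balance of directions depends on the scaling. The largest rises included Shh, a secreted morphogen, which was not well above background on any Ctrl array and was at least 8.69-fold higher in OGT_SCKO (adjusted p = 0.00028). Nrg1, a growth factor for Schwann cells, rose 19.5-fold (log2 fold change 4.29, SE 0.23), with 1 of 3 Ctrl arrays above background. Cyp4b1, a cytochrome P450, rose 16.1-fold (log2 fold change 4.01, SE 0.24). The largest falls included Actn3, a fast muscle actinin measured on all arrays, at 14.3-fold lower (log2 fold change -3.84, SE 0.21). The counts depend on the pools: with slide as a block 1226 genes changed, 1190 of them shared with the calls over both slides, and within slide 1 there were 407, both against Ctrl 2 alone. Of 110 calls among genes selected for naming other than Ogt, 52 ended with slide as a block and 76 within slide 1, and the named ones that ended with the block are given with their group. With slide as a random block, which keeps all 3 Ctrl pools in the comparison, 5244 genes changed. The estimated correlation between arrays of a slide was -0.14. A comparison with Ctrl 2 alone is less precise, so a call that ended there need not reflect the slide. Folds and bounds are those of the processed signal. With normexp, whose offset draws the log2 values of dim probes together, 34 of the 110 genes had a fold over 1.5 times smaller and 24 calls ended; Shh was 6.65-fold and Nrg1 8.04-fold higher and Actn3 8.12-fold lower. Leaving out Ctrl 1, Ctrl 2, Ctrl 3 or OGT_SCKO 3 gave 2451, 2558, 2105 or 1976 genes. Leaving out Ctrl 1, 2 or 3 ended 19, 26 or 30 of the 110 calls, and leaving out OGT_SCKO 1, 2 or 3 ended 9, 9 or 22. Of the genes named below, Prx, Ddx58, Gstm1, Cx3cr1, Kit, Tpsb2, Efnb3, Egfl7 and Abcb1a each passed in 1 of the 6 fits that leave out an array.

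Other genes with the largest rises were not well above background on any Ctrl array, so only bounds apply. Aqp5, a water channel, was at least 12.4-fold higher, Tcfl5 at least 8.14-fold and Prl7a1 at least 7.82-fold. Cwh43 was at least 7.07-fold higher, Retnlg at least 6.96-fold, Lama1, a laminin chain, at least 6.64-fold, Kcns1 at least 6.34-fold and Prl2a1 at least 3.52-fold. The fold of Aqp5 was 10.7 with slide as a block, and with normexp those of Aqp5, Tcfl5, Prl7a1, Retnlg, Lama1 and Kcns1 were 5.58, 5.79, 5.73, 5.73, 4.94 and 5.37, all under these bounds, which hold for the main processing only. Pdzk1ip1 gets no fold, since its probes disagree: 1 had a log2 fold change of 4.37 and the other 0.63 (limma adjusted p = 0.0986). Prolactin family members resemble each other, and their probes may share signal with paralogs. Among the falls, Plk5 was 29.6-fold lower with 2 of 3 OGT_SCKO arrays above background, and Crygs, a lens crystallin, 29.3-fold lower with 1 of 3. Mchr1 was 14.8-fold lower (1 of 3). Hs3st5 and Cyp2f2 were not above background on any OGT_SCKO array and were at least 3.51-fold and at least 2.81-fold lower. With normexp Plk5, Crygs and Mchr1 were 9.83-fold, 10.7-fold and 4.43-fold lower, and Hs3st5 and Cyp2f2 had folds of 3.47 and 2.20, under their bounds, and did not pass (adjusted p = 0.0899 and 0.194).

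Other large falls, in Mup genes (major urinary proteins) and genes of fat tissue, depend on single pools. Mup18 was 36.0-fold lower with 1 of 3 OGT_SCKO arrays above background, 15.2-fold without OGT_SCKO 2 and 76.1-fold without OGT_SCKO 3. Mup17 was 28.9-fold lower (1 of 3), 45.5-fold without Ctrl 1, 17.8-fold without Ctrl 2, 16.3-fold without OGT_SCKO 2 and 48.7-fold without OGT_SCKO 3. Mup19 was 20.6-fold lower (log2 fold change -4.37, SE 1.05), 13.5-fold without Ctrl 2, 9.21-fold without OGT_SCKO 2 and 35.8-fold without OGT_SCKO 3. The Mup genes are near-identical copies and a probe can read several of them. Car3 was 21.8-fold lower (2 of 3), 37.3-fold without Ctrl 1, 9.35-fold without OGT_SCKO 2 and 42.5-fold without OGT_SCKO 3. Adipoq was 18.9-fold lower (1 of 3), 31.6-fold without Ctrl 1, 9.99-fold without OGT_SCKO 2 and 36.35-fold without OGT_SCKO 3. Retn, an adipocyte hormone, was 13.8-fold lower (2 of 3), 6.63-fold without OGT_SCKO 2 and 22.1-fold without OGT_SCKO 3. Mup18, Car3, Mup19, Adipoq and Retn no longer passed without Ctrl 2 (limma adjusted p = 0.0717, 0.111, 0.0851, 0.0869 and 0.0988) or Ctrl 3 (0.0735, 0.118, 0.0828, 0.0978 and 0.105). Mup17 did not pass without Ctrl 3 (0.051), Mup19 without Ctrl 1 (0.0538) or Car3 without OGT_SCKO 1 (0.0519). With slide as a block, Mup18, Car3, Mup19, Adipoq and Retn did not pass either (0.0799, 0.111, 0.0787, 0.0958 and 0.0991), while their folds were larger, at 79.99, 45.4, 48.2, 35.9 and 26.3, and that of Mup17 was 76.3. With normexp Mup18, Mup17, Mup19, Car3, Adipoq and Retn had folds of 11.6, 8.50, 12.96, 13.6, 5.11 and 5.81, and Mup17, Car3, Adipoq and Retn did not pass (0.076, 0.0537, 0.08 and 0.0599). Raising values under an array's lowest value well above background to it, an alternative chosen after seeing the data, gave 21.1-fold for Mup18, 14.02-fold for Mup17, 12.7-fold for Adipoq and 11.1-fold for Retn.

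Genes that Schwann cells switch on after nerve injury were higher in OGT_SCKO nerves. Of 17 measured repair genes, 13 rose, 1 fell and 3 did not pass the test, and adjusting over the list alone gave the same counts. Igfbp2, a binding protein for insulin-like growth factors, rose 7.57-fold (log2 fold change 2.92, SE 0.12) and Gfap, a glial filament protein, 13.9-fold (log2 fold change 3.79, SE 0.25; 9.05-fold with normexp). Gdnf, a neurotrophic factor, was at least 2.61-fold and Btc, a ligand of the EGF receptor, at least 2.43-fold higher, neither being above background on a Ctrl array. Jun, which directs the injury response of Schwann cells, rose 2.64-fold (log2 fold change 1.40, SE 0.12, limma adjusted p = 0.000703). Against Ctrl 2 alone its log2 fold change was 1.40 too (adjusted p = 0.0167 with slide as a block and 0.0645 within slide 1). Cdh2, an adhesion molecule, fell 2.05-fold (adjusted p = 0.0561 with slide as a block). The list had a median log2 fold change of 1.21 (limma camera adjusted p = 1.38e-08; adjusted p = 0.149 with an estimated correlation). Its median was 1.43 against Ctrl 2 alone, with slide as a block or within slide 1 (camera adjusted p = 1.41e-08 and 7.88e-09).

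AP-1 genes, the family to which Jun belongs, were higher too. Of 12 measured members 5 rose, none fell and 7 did not pass the test; 6 were higher adjusted over the list alone. Fos rose 3.37-fold, Maff 2.53-fold and Atf3, induced by injury, 1.85-fold. The median was 0.33 (limma camera adjusted p = 0.00751; adjusted p = 0.279 with an estimated correlation), and 0.42 against Ctrl 2 alone, with slide as a block or within slide 1 (camera adjusted p = 0.0078 and 0.00611). Among 16 trophic factors 8 rose and 2 fell, with the same counts adjusted over the list alone. They share Shh, Gdnf, Clcf1 and Bdnf with the repair list. Fgf5 was at least 1.96-fold higher and Clcf1 had a log2 fold change of 1.67 (SE 0.13), while Igf2 fell (log2 fold change -2.24, SE 0.20). The trophic list's median was 0.38 (limma camera adjusted p = 0.00307; adjusted p = 0.527 with an estimated correlation), and 0.32 against Ctrl 2 alone, with slide as a block or within slide 1 (camera adjusted p = 0.0078 and 0.00611). Genes of immature and non-myelinating Schwann cells, which include Gfap and Cdh2, gave 4 higher and 2 lower of 13, also adjusted over the list alone. Id2 rose 3.43-fold and Cadm1 1.75-fold, and the list was not called (limma camera adjusted p = 0.172). Atf3, Id2 and Cadm1 did not pass with slide as a block (adjusted p = 0.0831, 0.0872 and 0.0946).

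Cell division genes rose as a group. All 16 measured members were higher, over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.08. Birc5 rose 2.61-fold, Ccnb1, the mitotic cyclin, 2.39-fold and Rrm2, an enzyme of nucleotide synthesis, 2.15-fold. Top2a rose 3.22-fold (2.03-fold with normexp) with 1 of 3 Ctrl arrays above background. The list passed the limma camera test (adjusted p = 5.02e-11; adjusted p = 0.318 with an estimated correlation). Against Ctrl 2 alone, with slide as a block or within slide 1, its median was 0.99 (camera adjusted p = 1.92e-09 and 2.81e-09).

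Myelin genes were slightly lower. Of 20 measured genes for myelin proteins and lipid enzymes, 18 had negative log2 fold changes, 3 fell and 17 did not pass the test, also adjusted over the list alone. Aspa, which breaks down N-acetylaspartate, fell 1.88-fold (log2 fold change -0.91, SE 0.11), Cmtm5 1.86-fold (log2 fold change -0.90 and with quantile normalisation -0.66, adjusted p = 0.00482) and Prx, periaxin, 1.44-fold. Cmtm5 and Prx did not pass with slide as a block (adjusted p = 0.0524 and 0.1301). Mbp, myelin basic protein, had a log2 fold change of -0.41 (SE 0.25, limma adjusted p = 0.254). The list's median was -0.33 (limma camera adjusted p = 0.0346; adjusted p = 0.719 with an estimated correlation), and -0.55 against Ctrl 2 alone, with slide as a block or within slide 1 (camera adjusted p = 0.0078 and 0.00611). With quantile normalisation the median was -0.07 and the call ended (adjusted p = 0.37), as it did without Ctrl 2 (0.106) or OGT_SCKO 2 (0.0921). Of 16 regulators of myelination, Pou3f2 rose 2.41-fold and 15 did not pass the test, also adjusted over the list alone. Egr2, a master regulator of myelination, had a log2 fold change of -0.04 (SE 0.15). That list was not called (limma camera adjusted p = 0.601), with a median of -0.05, a mean of 0.03 and an upward test.

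Lipid synthesis genes moved in both directions. Of 23 cholesterol genes 7 fell and 2 rose, with 8 lower adjusted over the list alone. Hsd17b7 fell 3.06-fold, Hmgcs1 1.93-fold and Fdps 1.88-fold, all enzymes of cholesterol synthesis. The camera test did not call the list (limma adjusted p = 0.562). Of 19 fatty acid genes 5 rose and 3 fell, also adjusted over the list alone. Fads2, a desaturase, rose 1.87-fold, Lpin1 1.71-fold and Me1 1.53-fold, and Pcx fell 1.58-fold. That list was not called (camera adjusted p = 0.578), with a median of -0.0011, a mean of 0.05 and an upward test. Among 20 glycolysis genes 3 rose and 2 fell, also adjusted over the list alone. Aldoc rose 1.94-fold and Pfkm fell 1.74-fold (camera adjusted p = 0.581). Lpin1, Me1, Pcx and Aldoc did not pass with slide as a block (adjusted p = 0.0759, 0.109, 0.0741 and 0.0528).

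Chemokines were higher. Of 14 measured chemokines and cytokines 5 rose and 9 did not pass the test; adjusted over the list alone, 7 were higher and 1 lower. Cxcl14 rose 12.9-fold (log2 fold change 3.69, SE 0.13), Cxcl10, an interferon-induced chemokine, 6.57-fold (log2 fold change 2.72, SE 0.48) and Ccl8 3.29-fold. The median was 0.52 (limma camera adjusted p = 0.00104; adjusted p = 0.279 with an estimated correlation), and 0.76 against Ctrl 2 alone, with slide as a block or within slide 1 (camera adjusted p = 0.000136 and 3.94e-05). Interferon response genes gave 4 higher of 19, also adjusted over the list alone. Usp18 rose 2.23-fold, Stat2 1.68-fold and Ddx58, an RNA sensor, 1.34-fold, and none of these 3 passed with slide as a block (adjusted p = 0.1301, 0.0504 and 0.162). Usp18 and Ddx58 also missed it with normexp (0.0569 and 0.0516). Their median was 0.42 (limma camera adjusted p = 0.00515; adjusted p = 0.719 with an estimated correlation), and 0.73 against Ctrl 2 alone, with slide as a block or within slide 1 (camera adjusted p = 3.77e-05 and 6.42e-07). Without Ctrl 2 the interferon call ended (adjusted p = 0.0543).

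Markers of immune cells changed in part. Of 21 macrophage markers 3 rose, also adjusted over the list alone: Cx3cr1 2.08-fold, Ctss, a lysosomal protease, 2.01-fold and Trem2 1.80-fold (list not called, limma camera adjusted p = 0.157). Among 11 T and NK cell markers, Klrd1 alone rose, by at least 2.17-fold, also adjusted over the list alone (camera adjusted p = 0.256). Neutrophil and mast cell markers gave 3 higher of 12, and 4 adjusted over the list alone. The members that rose were Retnlg, Kit (1.87-fold) and Tpsb2, a mast cell tryptase (1.94-fold). Cx3cr1, Trem2, Kit and Tpsb2 did not pass with slide as a block (adjusted p = 0.209, 0.0713, 0.204 and 0.271), nor Cx3cr1 and Tpsb2 with normexp (0.0627 and 0.078). The neutrophil genes S100a8 and Ly6g had log2 fold changes of 0.03 (SE 0.36) and 0.03 (SE 0.23). The list's median was 0.93 (limma camera adjusted p = 0.0269; adjusted p = 0.474 with an estimated correlation). It was 0.68 against Ctrl 2 alone, with slide as a block or within slide 1, where the call ended (camera adjusted p = 0.159 and 0.0599).

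Markers of fat and muscle were lower. Of 10 adipocyte markers 4 fell and 6 did not pass the test, with 7 lower adjusted over the list alone. Adipoq, the hormone adiponectin, Retn, Cidec (6.09-fold lower, 1 of 3 OGT_SCKO arrays above background) and Fabp4 (5.71-fold lower) fell. Without Ctrl 1 the folds of Cidec and Fabp4 were 9.32 and 8.84, and they did not pass without Ctrl 2 (adjusted p = 0.0543 and 0.0736) or Ctrl 3 (0.0641 and 0.0867), nor with slide as a block (0.0623 and 0.071), where their folds were larger (9.20 and 9.16). With normexp they were 2.42-fold and 4.66-fold lower and did not pass (0.155 and 0.0507). The median was -2.56 (limma camera adjusted p = 0.0418; adjusted p = 0.719 with an estimated correlation), and -3.20 against Ctrl 2 alone, with slide as a block or within slide 1 (camera adjusted p = 0.0202 and 0.00325). The call ended without Ctrl 2 (0.0659), Ctrl 3 (0.0975) or OGT_SCKO 1 (0.214). Of 11 skeletal muscle markers 8 fell, and 9 adjusted over the list alone. Acta1, the actin of skeletal muscle, fell 2.64-fold, Casq1 2.53-fold and Tnnc2 2.29-fold, and none of these 3 passed with slide as a block (adjusted p = 0.116, 0.0746 and 0.106). With normexp Acta1 and Tnnc2 did not pass (0.145 and 0.0731). The median was -1.20 (limma camera adjusted p = 0.00307; adjusted p = 0.474 with an estimated correlation), and -1.16 against Ctrl 2 alone, with slide as a block or within slide 1 (camera adjusted p = 0.0078 and 0.00522).

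**Figure D2:**
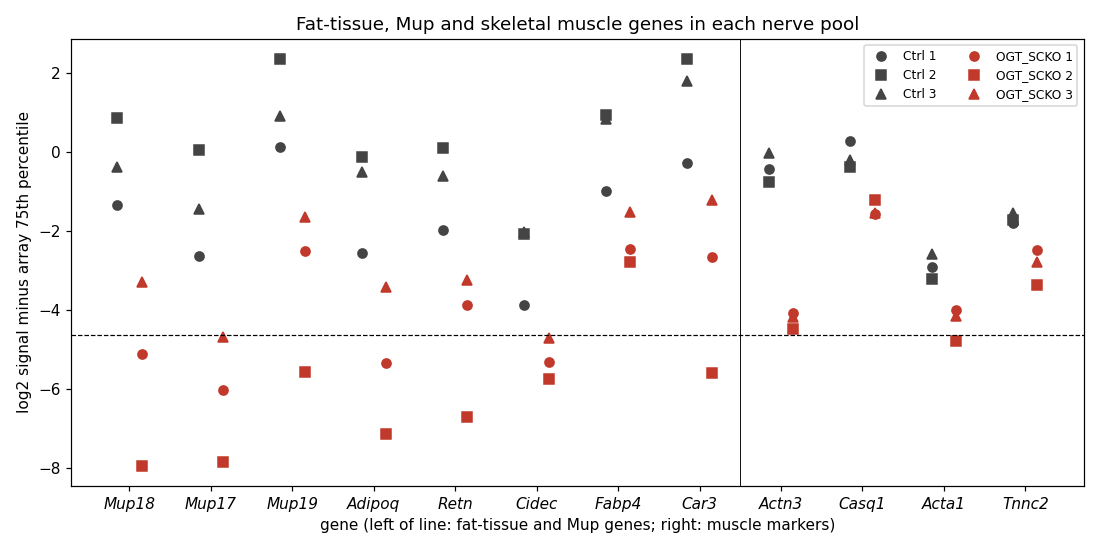
The vertical axis gives the log2 signal minus the array's 75th percentile of fat-tissue, Mup and muscle genes (horizontal axis) in each Ctrl (grey) and OGT_SCKO (red) pool, and the dashed line marks the highest of the 6 arrays' lowest values well above background. Actn3 fell from -0.40 ± 0.36 (SD, n = 3) to -4.24 ± 0.22 (SD, n = 3), while pools of a group differ widely in Mup and adipocyte genes.

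**Figure D3:**
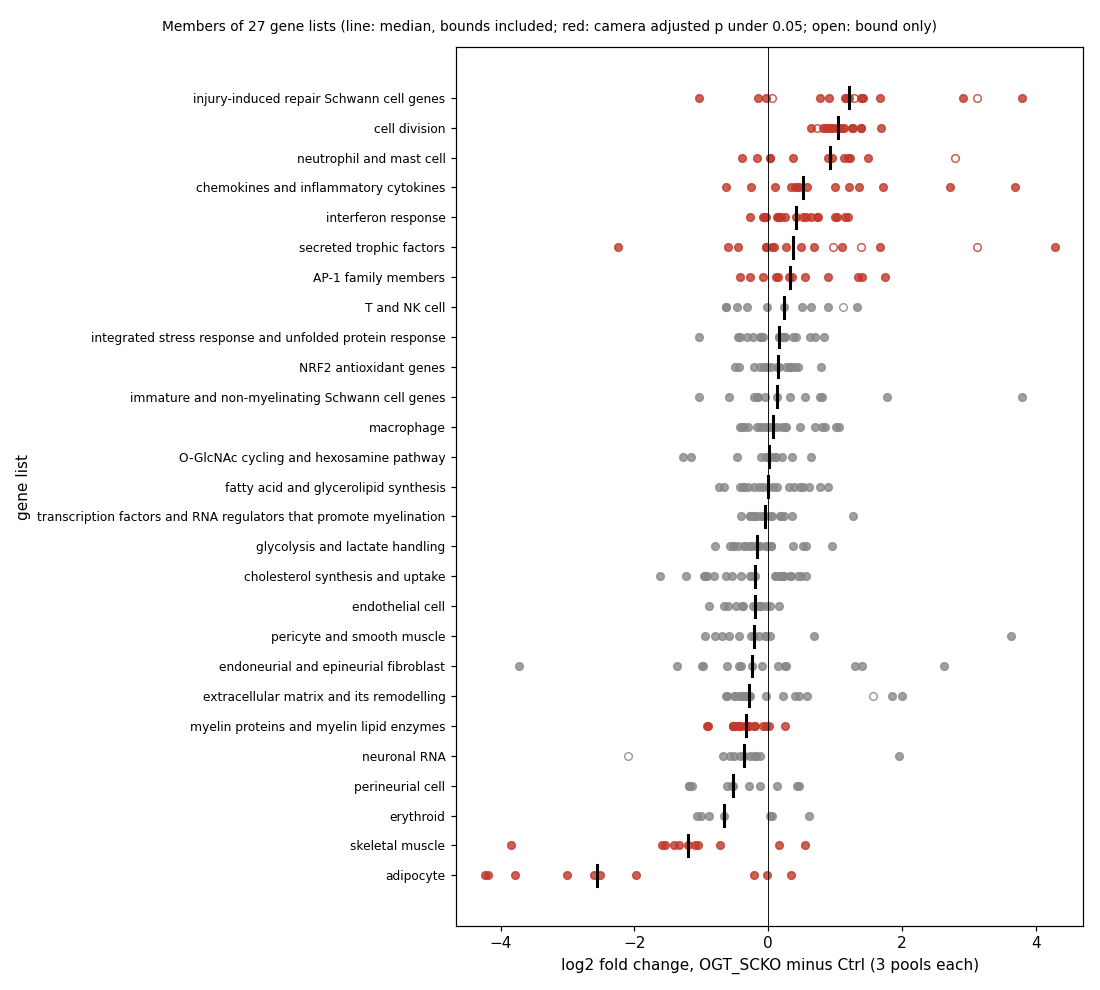
The horizontal axis gives the log2 fold change (OGT_SCKO minus Ctrl, 3 pools each) of each member of 27 gene lists, which form the rows. Lines are medians with bounds included, red lists have a camera adjusted p under 0.05, open circles are bounds, and members with no bound of at least 1 are left out. Repair genes and cell division genes lie highest, with medians of 1.21 and 1.04 on this scale, and adipocyte markers lowest at -2.56.

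Other cell types of the nerve gave mixed results. Of 11 perineurial markers 4 fell: Lypd2 2.27-fold, Msln 2.26-fold, Krt19 2.19-fold and Efnb3 1.53-fold; adjusted over the list alone, 1 was higher and 6 lower (limma camera adjusted p = 0.145). Of 14 endothelial markers 3 fell, also adjusted over the list alone: Abcb1a 1.58-fold, Vwf 1.52-fold and Egfl7 1.40-fold (camera adjusted p = 0.145). With quantile normalisation Egfl7 did not pass (limma adjusted p = 0.0721). Leaving out OGT_SCKO 2 gave a perineurial call (0.0482) and leaving out OGT_SCKO 3 an endothelial call (0.0146). Fibroblast markers gave 3 higher and 3 lower of 15, with 4 lower adjusted over the list alone (camera adjusted p = 0.935). Sfrp1, a Wnt antagonist, rose 6.22-fold, Thy1 2.65-fold, and Sfrp2 fell 13.2-fold with 2 of 3 OGT_SCKO arrays above background, and 20.02-fold without Ctrl 1, 20.09-fold with slide as a block and 6.01-fold with normexp. Of 13 mural markers 2 rose and 2 fell, with 4 lower adjusted over the list alone (camera adjusted p = 0.601). Cnn1, a smooth muscle protein, rose 12.4-fold (5.91-fold with normexp) with 1 of 3 Ctrl arrays above background, and the list had a median of -0.22, a mean of 0.02 and a downward test. Neuronal genes gave 1 higher and 3 lower of 11, with 4 lower adjusted over the list alone (camera adjusted p = 0.173). Uchl1 rose 3.89-fold and Syt1, a synaptic vesicle protein, was at least 4.26-fold lower, though 2.61-fold with normexp, where it did not pass (adjusted p = 0.149). Erythroid genes gave 1 higher and 1 lower of 7, with 4 lower adjusted over the list alone (camera adjusted p = 0.578). Efnb3, Abcb1a, Vwf, Egfl7, Thy1 and Syt1 did not pass with slide as a block (adjusted p = 0.241, 0.14, 0.0858, 0.191, 0.0605 and 0.0811), nor Efnb3 and Abcb1a with normexp (0.0752 and 0.0845).

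Matrix and stress genes were not called as lists. Of 19 extracellular matrix genes 6 rose and 2 fell, also adjusted over the list alone. Timp1, a protease inhibitor, rose 4.0-fold, Postn 3.62-fold, Fn1, fibronectin, 1.38-fold, and Tnc was at least 2.98-fold higher (2.62-fold with normexp), while Col4a1 fell (log2 fold change -0.51, SE 0.13). The matrix list had a median of -0.28, a mean of 0.20 and an upward test (limma camera adjusted p = 0.7). Of 18 stress response genes 3 rose and 1 fell, also adjusted over the list alone. Ddit3 rose 1.78-fold, Trib3 1.62-fold and Ppp1r15a 1.54-fold, and Shmt2, an enzyme of serine metabolism, fell 2.06-fold (camera adjusted p = 0.369). Of 16 NRF2 genes 3 rose and 1 fell, also adjusted over the list alone. Gclc, which starts glutathione synthesis, rose 1.73-fold (camera adjusted p = 0.145). The member called lower is Gstm1, by a probe that the files place on chromosome 5, while its probe on chromosome 3, where the gene lies, had a log2 fold change of -0.25 (limma adjusted p = 0.311). Tnc, Fn1, Ddit3, Trib3, Ppp1r15a, Gclc and Gstm1 did not pass with slide as a block (adjusted p = 0.069, 0.0979, 0.0807, 0.0733, 0.1001, 0.102 and 0.203). With an estimated correlation 0 of the 10 called lists passed; fry, which does not compare a list with other genes, called 10 lists. Those of fry included the cholesterol (adjusted p = 0.0178), NRF2 (0.00199) and perineurial (0.0208) lists, and not the myelin structure (0.0953), interferon (0.213) and adipocyte (0.154) lists. No list uncalled by camera over both slides was called with slide as a block or within slide 1, where the lowest adjusted p among them were 0.0853 and 0.0856, for perineurial markers.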

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

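All alternatives here were planned except raising values under an array's lowest value well above background to it, chosen after seeing the data. That gave 4304 changed genes, 1168 of them by at least 2-fold, and kept the direction of 4439 of the 4440. Every one of the 4440 changed genes kept its direction with quantile or median scaling, the deposited values, slide as a fixed or random block, slide 1 alone, the replicate block, other variance models, no filter, and each array left out. For many of these settings that was fixed in advance, since the Ctrl and OGT_SCKO values of all 4440 genes did not overlap. Leaving out arrays, slide 1 alone, the fixed slide block, the replicate block and other variance models could not reverse such a direction. Normexp kept the direction of 99.9% and the mean of a gene's probes that of 99.8%. The count of changed genes moved to 2722 with normexp, 2632 with no filter on dim probes, 1226 with slide as a fixed block, 407 within slide 1, 9456 with array weights and 1739 at an adjusted p under 0.01. Leaving out 1 array gave 1976 (without OGT_SCKO 3) to 5632 (without OGT_SCKO 1) genes. Without Ctrl 1, Ctrl 2 or Ctrl 3 the counts were 2451, 2558 and 2105. Fewer samples were fitted there and within slide 1, and the fixed slide block compares with Ctrl 2 alone. No filter tested 30303 genes. With slide as a random block 5244 genes changed. The cause of the shifts was not tested, and fewer samples alone would not give the rise seen without OGT_SCKO 1. Genes changed at least 2-fold numbered 699 with normexp and 407 within slide 1, where 69.8% of the changed genes were higher against 47.9% over both slides. Ogt within slide 1 had a log2 fold change of -1.32 and no longer passed (limma adjusted p = 0.0535). The called lists went from 10 to 0 with an estimated correlation, which allows for genes of a list varying together. Beyond the cases given in the report, the adipocyte call ended with normexp, no filter, a filter on all 6 arrays and array weights. The myelin call ended with no filter, the deposited values and array weights, the neutrophil and mast cell call with a filter on all 6 arrays and the deposited values, and the trophic call with a filter on all 6 arrays. With no filter the macrophage and NRF2 lists were called. Of the named genes other than Ogt, 52 no longer passed with slide as a fixed block and 76 within slide 1, the control arm being Ctrl 2 alone in both. Examples are Mup18, Car3, Mup19, Adipoq and Retn, with adjusted p of 0.0799, 0.111, 0.0787, 0.0958 and 0.0991 under the block, where their folds were larger. With normexp 24 of the 110 did not pass and 34 had a fold over 1.5 times smaller.

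Whether the replicate numbers pair the pools is not given in the sources used here. Same-numbered pools had correlations of deviations of -0.27, -0.53 and 0.06. These cannot decide it, since differences between arrays also enter them. With the replicate block 1480 genes changed. The scan was the same split as the slide, so it was not run separately, and camera takes no random block, so lists were not tested with slide as a random block. Signal over background limits 210 genes measured by no probe on a Ctrl array and by 1 on all OGT_SCKO arrays, and 48 genes the other way, to bounds.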

Other observations

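Each pattern below was noticed in the data first; the tests of sample splits, fat tissue, sex and Actn3 were chosen after their results were seen, and those of the other muscle markers and of myelin before.

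Beyond the fixed lists, 210 genes were not well above background by any probe on a Ctrl array and were on all OGT_SCKO arrays, and 172 of them changed in limma; 70 had a bound of at least 2-fold. In the other direction there were 48 genes, 43 of them changed and 34 with a bound of at least 2-fold. Both sets were picked by their signal on these same arrays, so their limma calls are not separate support. Of 379 groups of genes sharing a symbol stem, with at least 6 members each and formed after the data were seen, limma camera called 4. Cdca genes, named for cell division, were higher (6 of 7 rose, median log2 fold change 1.02, adjusted p = 0.000825). Mup genes were lower (8 of 9 fell, median -3.54, adjusted p = 0.015). Olfr genes, the odorant receptors, had a median of -0.52 over 173 measured members (camera adjusted p = 0.000279). Of these 25 fell, against 2312 of all 19046 genes tested. Vmn genes, the vomeronasal receptors, had a median of -0.58 over 40 members, of which 7 fell (adjusted p = 0.0264). With quantile normalisation the medians were 1.04, -3.40, -0.43 and -0.49. With an estimated correlation the adjusted p of each was at least 0.976. Members of such families are similar in sequence, and many Olfr and Vmn probes lie near background. After scaling, the lowest value well above background ran from -5.27 to -4.64 in Ctrl and from -5.77 to -4.98 in OGT_SCKO. A fall of Olfr and Vmn genes cannot be told apart from this difference here.

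The real split of the 6 pools gave 4440 changed genes, and the highest of the other splits gave 0. With 1 of 10 splits reaching that count, the splits are too few for a share under 0.05.

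The fall of fat markers and Mup genes may follow from unequal amounts of fat tissue in the pools. The 15 adipocyte and Mup genes at least 2-fold lower varied together within groups, with a mean pairwise correlation of 0.80 (0.91 among the 7 adipocyte genes alone, given apart because Mup copies can share signal), at percentile 100 of 1000 random sets matched on signal (median 0.02). A true loss of fat cells in OGT_SCKO nerves would give the same co-variation and stays open, as does genotype. The adipocyte genes Lipe, Plin4 and Pnpla2 had log2 fold changes of -0.21, -0.01 and 0.35, and the nerve may express these without fat. The pools differed in sex make-up: Ddx3y, Y-linked, ran from -2.82 in Ctrl 1 to 0.49 in OGT_SCKO 3. Xist was not well above background in Ctrl 2 and OGT_SCKO 3, which held the highest values of most Mup genes within their groups. The values argue against sex make-up as the source of the whole fall, while a part stays open. With Ddx3y as a covariate the mean difference of the 15 genes was -3.47 (95% interval -6.43 to -0.50) against -3.42 without. With Xist it was -3.42 (-5.51 to -1.33). For the 7 adipocyte genes alone, the interval with Ddx3y was -6.40 to -0.09. These fits rest on 6 pools and assume a straight-line relation.

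For muscle, Actn3 fell further than any other measured marker of skeletal muscle. The upper end of its 95% interval was -3.34, below the lower end of the interval of each of the other 10 measured markers, the lowest being -2.50 for Myh4 (with normexp, -2.25 against -1.94). These intervals argue against less muscle as the whole source of the Actn3 fall only if the other markers come from muscle alone. The nerve may express some of them without muscle, which would make their falls smaller, so less muscle stays open for Actn3. Acta1, Myh4, Mylpf and Myl1 also lie nearer background, with mean log2 signals of -3.90 to -3.58. A large fall would be measured less fully there. The means of the other markers compared ran from -2.28 (Tnnc2) to 1.28 (Pvalb). For the 7 other markers that fell, the amount of muscle and a change in the nerve cannot be told apart either. Their co-variation within groups, with a mean pairwise correlation of 0.30, lay at percentile 94.8 of the random sets, just short of the 95th percentile set beforehand. Atp2a1, abundant in fast muscle, had a log2 fold change of 0.17.

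The small fall of the myelin list may come from a trend with signal strength between the arrays. Its median of -0.33 lay at percentile 24.97 of 10000 random lists matched on signal, whose median was -0.30 and whose 5th percentile was -0.37, and the list's median was -0.07 with quantile normalisation. These genes are among the brightest on the arrays. A loss of myelin transcripts in OGT_SCKO nerves stays open, since a trend shared by bright genes and a change of many bright nerve genes look alike here. Among the list's members that fell, Aspa had a log2 fold change of -0.83 with quantile normalisation (limma adjusted p = 0.00416), Cmtm5 -0.66 (adjusted p = 0.00482) and Prx -0.20 (adjusted p = 0.241).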
